A study of Homo sapiens with 9 samples.

How the data were processed

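Total RNA of HEK293 cells, a human embryonic kidney line, was labelled with biotin and measured on 9 Illumina bead arrays. Per the labels, 3 arrays came from wild-type cells, used here as the control group, 3 from cells with a short hairpin RNA against AMOT and 3 from cells with a short hairpin RNA against YAP1, each set from 3 individual experiments. The sample titles call the hairpin groups knockouts, whereas their sources name hairpins and the design text says knockdown; they are called knockdowns here. No group with a control hairpin is labelled. Each comparison with the controls may therefore hold effects of a hairpin vector and of any selection, beside those of the lowered target transcript. The labels do not tell hairpins of the same target apart. Whatever is particular to a hairpin or a line therefore cannot be separated from lowering its target, also in the comparison between the knockdowns. When the cells were collected and how the hairpins were delivered are not given in the sources used here.

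The deposited table of 47231 probes gives for each array a bead-summarised intensity on a linear scale, neither background-corrected nor normalized between arrays. Beside each intensity, per the file headers, stands a detection p-value, the probability of such a signal among the negative control beads. The control beads themselves, the slide of each array and the scanning software were not given in the sources used here. A second deposited table, the series matrix, holds 20062 of these probes as linear intensity values that the authors had normalized between arrays by an unstated method and filter. Its column medians were 548.478, 548.607 and 548.607 for the controls, 548.478, 548.607 and 548.478 for the AMOT knockdown and 548.35, 548.147 and 548.108 for the YAP knockdown. Within each array its probes had the same order as the unprocessed signals (rank correlation 1 across probes), so it was used only as an alternative.

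Gene symbols came from a table of the probes of the series matrix, in which 15467 probes had 1 symbol, 4 had several and 4591 probes of the matrix had no entry. Of the 22375 probes tested, 15261 had 1 symbol, for 11493 genes, and 7114 (31.8%) stayed unnamed, 2669 of the tested probes being outside the series matrix. Unnamed probes entered the counts of probes and no gene list. Of the named probes, 15252 were matched by gene number to the reference gene table of the human assembly GRCh38.p14, which gave chromosomes and positions; positions are those of the genes, since probe sequences were not used here.

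Signals were processed in R 4.3.3 with limma 3.58.1. Background was removed with the normal-exponential model, with the negative control distribution inferred from the detection p-values, an offset of 16 was added, and the arrays were quantile-normalized and put on the log2 scale (limma's neqc). The offset holds changes of dim probes towards 0. Probes were tested when their detection p was under 0.05 on at least 3 of the 9 arrays. One linear model with a mean for each of the 3 groups was fitted to all 9 arrays, with 6 residual degrees of freedom and 3.53 prior degrees of freedom from the moderation of variances. Limma's moderated 2-sided test was applied to AMOT knockdown minus control, YAP knockdown minus control and AMOT knockdown minus YAP knockdown, the last being the test of whether the 2 knockdowns differed. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Errors beside fold changes are standard errors of that fit with 3 arrays per group, and they measure the spread between the arrays of a group; the number of arrays limits the precision. Where a probe was undetected on all arrays of the dimmer group, the change is given as a lower bound, the brighter mean over the level at which detection ended. Where a probe was detected on some arrays of a group but its mean lay under that level, the change is the fitted one and its size depends on the background and offset. This holds for CYP4X1, ANKRD1, JAG1 and LUM and the brighter probe of STMN2 in the controls, GALC, SLC43A2, MAGEA6, PPIL4 and PHLDA3 in the AMOT knockdown, and TKFC, CHAC1 and LUM in the YAP knockdown.

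Quantile normalization gives the arrays one distribution, so changes are relative to the whole of the measured transcripts and a change of total RNA per cell would not be seen. Under median scaling, cyclic loess or no background correction, no contrast moved the median log2 fold change of all probes by over 0.1. Each of these settings itself brings the arrays to a common level, so they are no check on a change of total RNA.

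In total, 35 gene lists were written and 34 had a measured member; none of the 10 endothelial marker genes was measured. Each gene was represented by its probe with the highest mean. Lists were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, and adjusted over the 34 lists. Beside it stand camera with a correlation estimated from the 9 arrays and fry, which tests whether a list moves on balance in 1 direction and does not compare it with other genes. Members were counted past the threshold over all probes and adjusted over the list alone. The overlap of the knockdowns was set against 100 simulated sets of 9 unchanged arrays, with both groups compared with the same simulated controls. Their noise was independent for each probe and array, at the moderated spread pooled over the groups. This was done since both contrasts share the 3 control arrays, which are too few to give each contrast controls of its own.

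The groups, the tests of the comparisons, their thresholds, the gene lists, the rule for named genes and the alternatives named below, except the one on chromosome 17, were fixed before the data were examined. The scan of neighbouring genes and some tests of explanations were chosen later, as said where they are given. The rule named AMOT and YAP1; per knockdown the 12 genes that rose most and the 12 that fell most among those past the threshold whose 3 knockdown arrays all lay on 1 side of all 3 control arrays; the 6 highest and 6 lowest between the knockdowns; 8 rising and 8 falling genes shared by both and 5 each way with opposite changes; and up to 4 members past the threshold per gene list, with CCN1, CCN2 and ANKRD1 always. For 3 against 3 arrays, groups of unchanged probes lie apart in 10% of cases. Symbols that are only clone or open reading frame names were passed over. The values of a named gene are those of the probe the rule picked, often the one with the largest change, and other probes are given for many, not all, of the genes where they stood apart; 56 genes in the AMOT knockdown and 72 in the YAP knockdown, of 3032 genes with more than 1 tested probe, had probes past the threshold in both directions.

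The procedure was tested on simulated data with the spread of these arrays. In 5 draws with 200 changed probes each, 15.1% of changes of log2 0.5, 88.4% of changes of log2 1 and 100% of changes of log2 2 were recovered in the simulated AMOT contrast, and 3.27% of calls were false. A list shifted by log2 0.5 was called in 20 of 20 draws, with at most 2 other lists called in a draw. The probe draws changed 200 of 22375 probes, against 7846 called in the real AMOT contrast, so their adjusted threshold was stricter than in the data. Noise was independent for each probe and the normalization was not rerun. The list draws therefore held no correlation between genes, and these shares need not hold for the real arrays.

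The alternatives were no background correction, background correction without the detection p and an offset of 50, median scaling and cyclic loess in place of quantile normalization, no filter on dim probes, detection p under 0.01 on all 9 arrays, the series matrix values, the replicate number as a fixed or a random block, only the 2 groups compared, a trended and robust variance prior, array quality weights, adjusted p 0.01, a minimum of 1.5-fold, and each array left out in turn; for the lists also camera with an estimated correlation, fry and the mean of a gene's probes. Camera takes no random block, so that setting used camera's preranked form on the moderated statistics of the block's fit. Its list calls may differ through the block or through the change of test. Leaving out chromosome 17 genes was added after the data were seen. A block for the slide was not run because no column names one, and a second probe for AMOT or YAP1 could not be tried because each had 1 named probe.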

Results

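Transcript levels were measured on 9 bead arrays of HEK293 cells, 3 from wild-type controls, 3 from cells with a hairpin against AMOT and 3 from cells with a hairpin against YAP1. AMOT encodes angiomotin, a scaffold protein of cell junctions that binds the transcriptional coactivator YAP, the product of YAP1, which acts with TEAD factors downstream of the Hippo kinases. Median raw signals were 185, 208 and 188 in the controls, 185, 177 and 175 in the AMOT knockdown and 182, 184 and 180 in the YAP knockdown. Probes with a detection p under 0.05 numbered 19831, 20397 and 20257 in the controls, 20827, 20876 and 22187 in the AMOT knockdown and 20866, 21123 and 21709 in the YAP knockdown. All 6 knockdown arrays lay above all 3 controls. The first principal component of the 22375 tested probes held 50.1% of the variance and parted the controls from both knockdowns. The next held 21.4% and parted the knockdowns from each other.

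AMOT, on chromosome X at 112774877 to 112840831 (GRCh38.p14), had log2 levels of 14.33, 14.32 and 14.21 in the controls. In the AMOT knockdown its levels were 9.94, 10.05 and 10.21, an 18.7-fold lower mean (log2 change -4.22, SE 0.10, n = 3 per group, limma adjusted p = 3.8e-08). In the YAP knockdown they were 13.66, 13.72 and 13.76, a small fall by 0.57 on the log2 scale (adjusted p = 0.0017). YAP1, on chromosome 11 at 102110447 to 102233424, had levels of 10.63, 10.71 and 10.64 in the controls and 8.79, 8.79 and 8.93 in the YAP knockdown, 3.54-fold lower (log2 change -1.82, SE 0.10, adjusted p = 3.2e-06). Its levels in the AMOT knockdown were 10.48, 10.52 and 10.74, a log2 change of -0.08 that did not pass the test (adjusted p = 0.57). Each gene had 1 named probe.

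**Figure D1:**
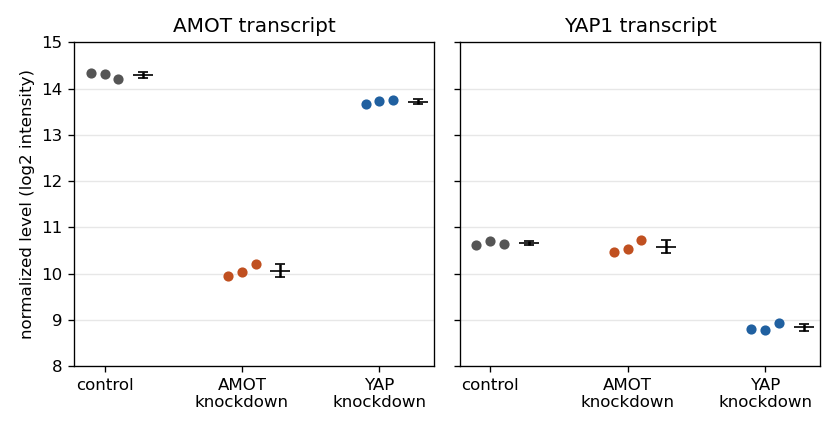
Normalized log2 intensity of the AMOT and YAP1 probes on each array, by group, with points for the 3 arrays and their mean and SD. AMOT lay at 14.29 in the controls against 10.06 in its own knockdown, and YAP1 at 10.66 against 8.84 in its own knockdown.

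The fixed list of YAP/TAZ-TEAD target genes held 13 measured members. ANKRD1, a nuclear protein of muscle and a widely used reporter gene of YAP activity, rose in the AMOT knockdown to a mean log2 level of 8.28, a fitted change of 2.5 (SE 0.18, n = 3 per group, adjusted p = 1.6e-05) and by 0.67 in the YAP knockdown, and the knockdowns differed by 1.83. Its control mean of 5.78, with 2 of 3 arrays detected, lay under the limit of detection, so the sizes of its changes against the controls are uncertain. The matricellular genes CCN2 and CCN1 rose in the AMOT knockdown by 0.84 and 0.89, and FJX1, a Golgi kinase, by 0.81. In the YAP knockdown CCN2 fell by 0.39 on the log2 scale, CCN1 stood at -0.09 (adjusted p = 0.63) and FJX1 at 0.15. The difference between the knockdowns was 1.23 for CCN2 and 0.98 for CCN1, both past the threshold. GADD45A, which is also on the list of p53 targets, rose by 0.54 in the AMOT knockdown and by 1.27 in the YAP knockdown, and ARHGEF17, undetected in the controls, was at least 1.13-fold and 1.08-fold higher. In all, 6 members rose and 7 were not called in the AMOT knockdown. In the YAP knockdown 3 rose and 1 fell. The counts were the same adjusted over the list alone. Between the knockdowns 4 members were higher in the AMOT than in the YAP knockdown and 1 lower, the same over the list alone. The list as a whole was called in no comparison by camera (adjusted p = 0.14 for AMOT, 0.63 for YAP and 0.27 between them) and passed in each by fry (9.9e-04, 0.031 and 0.016). The CCN2 and ANKRD1 calls in the YAP knockdown were not stable: ANKRD1 no longer passed without YAP knockdown array 2 or 3, and CCN2 no longer passed without control 2 or 3, AMOT knockdown array 2 or any 1 of the 3 YAP knockdown arrays. CCN2 also did not pass under median scaling, cyclic loess or no background correction.

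Of the 23 measured genes of the Hippo pathway and the angiomotin family, 1 rose and 5 fell in the AMOT knockdown, AMOT itself among them, and 4 rose and 5 fell in the YAP knockdown. MOB1A, a cofactor of the LATS kinases, fell by 0.80 on the log2 scale in the AMOT knockdown and again by 0.80 in the YAP knockdown. VGLL4, a competitor of YAP for TEAD factors, rose by 1.08 and TEAD3 by 1.02 in the YAP knockdown, and TEAD2 fell by 0.58 in the AMOT knockdown. The list was not called by camera (adjusted p = 0.20 in the AMOT knockdown, 0.63 in the YAP knockdown, 0.22 between them) and passed in each by fry (5.9e-05, 0.024 and 3.0e-04). With the replicate number as a random block, camera's preranked form called it in the AMOT knockdown (adjusted p = 0.0094). It did so between the knockdowns too (0.034). The block and the change of test were not separated. AMOT and YAP1, the targets of the hairpins, are members, so these values hold the knockdowns themselves, and the list was not tested without them. Adjusted over the list alone the counts were the same for each knockdown, and between the knockdowns 7 members in place of 5 were lower in the AMOT knockdown. Among 15 genes of tight junctions and apical polarity, PARD3 and LIN7C were the members past the threshold in the AMOT knockdown, PARD3 at least 1.21-fold higher and LIN7C lower by a log2 change of -0.62. In the YAP knockdown 4 rose, among them PARD6A by 1.01 and the junction protein CGN by 0.64, and 1 fell, 3 and 1 over the list alone (adjusted p for the list by camera 0.62, 0.63 and 0.24 between them, by fry 0.025, 5.3e-04 and 1.4e-04).

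In the AMOT knockdown the cytochrome P450 gene CYP2E1 rose from a log2 level of 5.97 in the controls, near the limit of detection, to 10.43 (log2 change 4.45, SE 0.16, n = 3 per group, adjusted p = 6.7e-07). CYP4X1, of the same family, had a fitted change of 4.70 (SE 0.26, adjusted p = 4.3e-06), but its control mean of 5.62 lay under the limit of detection, with 1 of 3 control arrays detected, and its other probe stood at 1.73. HSPB8, a small heat shock protein, rose by 3.34, and ISG15, a ubiquitin-like protein induced by interferon, was at least 7.64-fold higher. The phospholipase PLA2G4C was at least 7.64-fold higher, the membrane receptor PAQR6 at least 5.80-fold, KRCC1 at least 5.57-fold and the channel subunit CACNG6 at least 4.73-fold. CFAP70 rose by 3.00 and the hair keratin-associated gene KRTAP19-1 by 2.91. HDHD5-AS1 rose by 3.07 by 1 probe and by 0.89 by another, and another probe of KRCC1 rose by 1.35. DNAH14 was at least 5.33-fold higher by 1 probe, with its other probes at 2.25, 0.79 and -0.77. Among the falling genes BEX1, a small adaptor protein of neural tissue, went from a log2 level of 11.01 to undetected on all 3 arrays, at least 36.1-fold lower (adjusted p = 4.6e-09), although another of its probes stood at -0.37. TOM1L2, a protein of endosomal sorting, changed by -4.29 by 1 probe and by -1.40 by another. The lysosomal galactosylceramidase GALC changed by -3.26. The fatty aldehyde dehydrogenase ALDH3A2 changed by -2.49, with other probes at -1.29 and -1.39. CRISPLD1 was at least 3.81-fold lower and the folate carrier SLC19A1 at least 4.01-fold. B9D1, a protein of the ciliary transition zone, changed by -2.36, the amino acid transporter SLC43A2 by -2.33, the RNA-binding coactivator RBM14 by -2.29, MAGEA6 by -2.25 and the ATP synthase assembly factor ATPAF2 by -2.21.

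In total 7846 of 22375 probes (35.1%) changed in the AMOT knockdown, 3931 up and 3915 down; 949 rose and 476 fell by at least 2-fold. These covered 2692 genes with a rising and 2587 with a falling probe.

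TOM1L2, ALDH3A2, B9D1 and ATPAF2 lie near each other on chromosome 17. Of the 57 measured genes from SNORD65 to SARM1 (chromosome 17, 16441226 to 28404049), 32 fell and 1 rose in the AMOT knockdown, with a median log2 change of -0.61, and 49 of the 57 values were below 0. In the YAP knockdown 14 of them fell and 9 rose, with a median of -0.09. A further 21 genes from MYO19 to SPMAP1 (chromosome 17, 36495636 to 38841438), among them the proteasome gene PSMB3, had a median of -0.67 in the AMOT knockdown and -0.06 in the YAP knockdown. Of these, 14 fell in the AMOT knockdown. The stretches were found by a scan of running medians over 21 neighbouring genes, chosen after the values of TOM1L2 and its neighbours were seen.

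**Figure D2:**
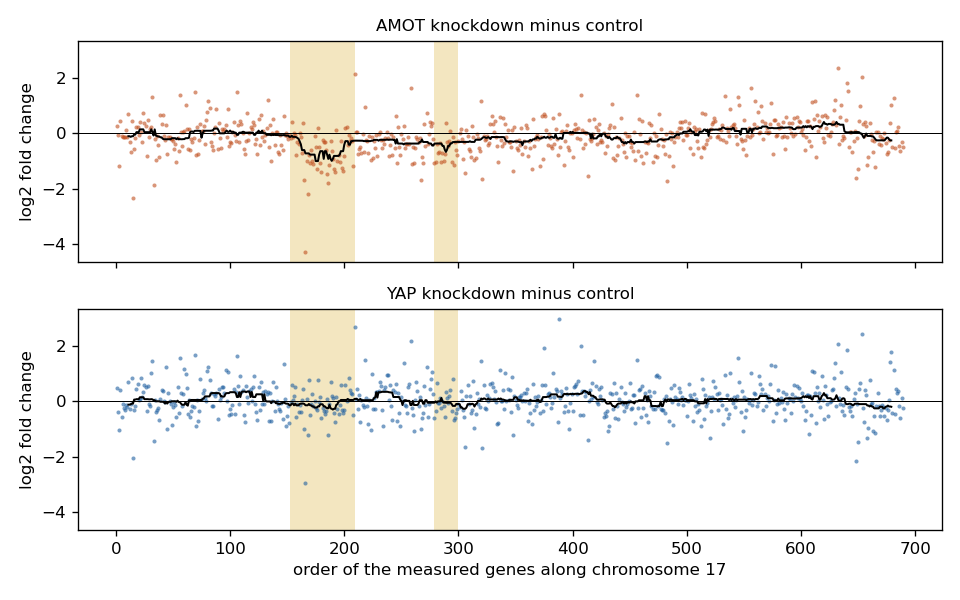
Log2 fold change of each measured gene of chromosome 17 in order along the chromosome, for the AMOT knockdown (top) and the YAP knockdown (bottom) against controls, with the running median of 21 genes as a line and the stretches with low running medians in the AMOT knockdown shaded. The running median falls to -1.005 in the AMOT knockdown around TOP3A; the median over the first shaded stretch was -0.09 in the YAP knockdown.

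Of the gene lists, 5 were called by camera in the AMOT knockdown. Proteasome genes were lower (adjusted p = 4.9e-05; adjusted p = 0.13 with an estimated correlation). Of 25 members 15 fell and 10 were not called, 20 falling when adjusted over the list alone. PSMB3 stood at -1.14, PSMD11 at -1.08 and PSMD3 at -0.89, all of chromosome 17. With genes of chromosome 17 left out, a choice made after the data were seen, the list was still called (adjusted p = 5.2e-04). Oxidative phosphorylation genes were lower (adjusted p = 2.9e-04; adjusted p = 0.15 with an estimated correlation), 13 of 27 falling and 15 over the list alone. UQCRB of complex III stood at -1.49 (other probes at -0.33 and -0.62) and ATP5MC1 of the ATP synthase at -0.96. Ribosome biogenesis genes were lower (adjusted p = 3.0e-04; adjusted p = 0.067 with an estimated correlation), 12 of 21 falling and 13 over the list alone. Among them were BOP1 at -1.34, UTP20 at -1.25, RRP9 at -0.80 and MYC at -0.41.

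Neuronal genes were higher in the AMOT knockdown (adjusted p = 2.9e-04; adjusted p = 0.067 with an estimated correlation), with 11 of 17 rising and 1 falling, the same adjusted over the list alone. DPYSL3, a protein of growing axons, rose by 1.95, the neuronal enolase ENO2 by 1.37 and the adhesion molecule NCAM1 by 1.23, while the neurofilament gene NEFM fell by 0.94 on the log2 scale. The list's median log2 change was 0.80, and 0.78 with the 3 members undetected in the controls set at their lower bounds. Histone genes were higher (adjusted p = 0.010; adjusted p = 0.13 with an estimated correlation), with 9 of 14 rising and 2 falling, 9 and 3 over the list alone. H2BC5 rose by 2.22 and H2AC18 by 1.22, and H4C8 and H2AC6, undetected in the controls, were at least 2.33-fold and 1.43-fold higher. H4C3 and H3-3A changed by -0.87 and -0.35. The histone median was 0.65, and 0.56 with the 2 bounded members at their bounds, and the call was lost when detection p under 0.01 was asked on all 9 arrays (adjusted p = 0.053; over the alternatives from 3.8e-06 to 0.13).

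Single members moved in lists that camera did not call. CCND1, the G1 cyclin D1, fell in the AMOT knockdown by 2.13 on the log2 scale (SE 0.11, limma adjusted p = 3.1e-06). The Wnt target list split into 4 rising and 5 falling of 12, 6 and 5 over the list alone (camera adjusted p = 0.73). Its median was 0.14, or 0.04 with the 2 bounded members at their bounds, and its mean was -0.08. The Notch effector HES5 rose by 2.49, in a list with 5 of 12 rising and 1 falling by either count (camera adjusted p = 0.20). That list was called by camera's preranked form with the replicate number as a random block (adjusted p = 0.032). In the list of epithelial and mesenchymal genes (adjusted p = 0.22) the hyaluronan receptor CD44 was at least 2.36-fold higher, EPCAM rose by 1.32 and vimentin, VIM, by 0.87. Of 25 genes of the extracellular matrix and integrins, 12 rose and 3 fell, 13 and 6 over the list alone (adjusted p = 0.18), with LAMA1 up by 1.25 and COL5A2 down, at -1.24. That list was called when detection p under 0.01 was asked on all 9 arrays (adjusted p = 0.0037; over the alternatives from 4.1e-04 to 0.43).

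In the YAP knockdown CHGB, the granule protein chromogranin B, was at least 33.6-fold higher than on the control arrays, where it was undetected, with a mean log2 level of 11.02 (n = 3 per group, adjusted p = 7.4e-09). SNAP25, a component of the synaptic vesicle fusion machinery, was at least 10.5-fold higher, STMN2, a microtubule regulator of axons, at least 11.2-fold, ACTL6B, the neuronal subunit of a chromatin remodelling complex, at least 10.1-fold and SCG3, a secretogranin, at least 8.29-fold. Another probe of SCG3 rose by 1.83, less than that bound. NMNAT2, an axonal enzyme of NAD synthesis, was at least 10.7-fold higher and the netrin receptor UNC5A at least 6.59-fold. KRTAP19-1 rose by 4.35, KRTAP19-6 by 3.97 and TCEAL7 by 3.91, and KRTAP20-2 and KRTAP19-4 were at least 7.65-fold and 6.09-fold higher. Among the falling genes TOM1L2 changed by -2.94, with another probe at -1.56, ITGB3BP, a centromere protein, by -2.45, RBM14 by -2.42, SLC38A10 by -2.18, the neuropeptide gene GAL by -2.16, ZNF326 by -2.12, with another probe at -1.52, and SLC43A2 by -2.04. SCARNA14 was at least 4.83-fold lower, MED23 at least 3.33-fold and PPIL4 at least 3.21-fold. HNRNPA1 changed by -2.17 and TRIOBP by -2.09 by 1 probe each, with another probe of HNRNPA1 at 0.04 and others of TRIOBP at -0.86 and 0.44, and MED23 had other probes at -0.57 and 0.22.

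In total 8338 of 22375 probes (37.3%) changed in the YAP knockdown, 4147 up and 4191 down; 957 rose and 539 fell by at least 2-fold. With median scaling in place of quantile normalization the split was 3803 up and 2478 down.

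Of the gene lists, 8 were called by camera in the YAP knockdown. Neuronal genes were higher (adjusted p = 1.2e-05; adjusted p = 0.030 with an estimated correlation), with 11 of 17 rising and 1 falling, the same adjusted over the list alone. Beside CHGB, SNAP25, STMN2 and SCG3, the granule protein CHGA rose by 2.98, the synaptic vesicle protein SYP by 2.36, ENO2 by 2.09, the intermediate filament INA by 1.36 and the tubulin TUBB3 by 1.26. The ubiquitin hydrolase UCHL1 fell by 0.58 on the log2 scale, and the median of the list was 1.26, also with the 3 members undetected in the controls at their bounds. Target genes of p53 were higher (adjusted p = 0.0012; adjusted p = 0.073 with an estimated correlation), with 12 of 20 rising and 1 falling, the same over the list alone. The stress cytokine GDF15 was at least 5.38-fold higher, the cell cycle inhibitor CDKN1A rose by 2.40 (SE 0.14, n = 3 per group, adjusted p = 4.3e-06), the DNA damage binding protein DDB2 by 1.54 and PHLDA3 by 1.31. Notch target genes were higher (adjusted p = 0.011; adjusted p = 0.16 with an estimated correlation), with 7 of 12 rising and 8 over the list alone. HES5 rose by 1.65, NOTCH3 by 1.42, the ligand JAG1 by 1.18 and NOTCH1 by 1.03.

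**Figure D3:**
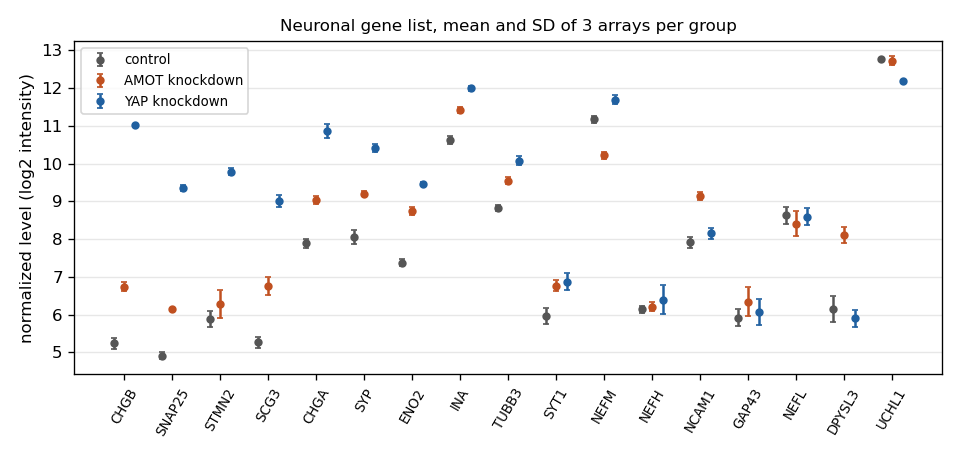
Normalized log2 intensity of the 17 measured members of the neuronal gene list, as mean and SD of the 3 arrays of each group. CHGB, SNAP25, STMN2 and SCG3 lay near the floor in the controls and well above it in the YAP knockdown, CHGB at 11.02, and STMN2 is drawn for its brighter probe.

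Ribosome biogenesis genes were lower in the YAP knockdown (adjusted p = 6.7e-07; adjusted p = 0.029 with an estimated correlation). Of 21 members 15 fell, 19 over the list alone. BOP1 and NOLC1 stood at -1.06, RRP12 at -1.04 and UTP20 at -0.99. Proteasome genes were lower (adjusted p = 1.7e-05; adjusted p = 0.13 with an estimated correlation), with 15 of 25 falling and 17 over the list alone. Among them were PSMD11 at -1.09, PSMD12 at -1.07 and PSMC4 at -0.92. Oxidative phosphorylation genes were lower (adjusted p = 3.4e-04; adjusted p = 0.16 with an estimated correlation), 13 of 27 falling by either count, with UQCRB at -1.29 (other probes at 0.09 and -0.44) and NDUFA9 at -0.81. Genes of G2/M and mitosis were lower (adjusted p = 0.0022; adjusted p = 0.16 with an estimated correlation), 12 of 28 falling and 1 rising, 13 and 1 over the list alone. The motor protein KIF20A stood at -0.98, the checkpoint activator CDC20 at -0.78, the mitotic kinase PLK1 at -0.62 and PTTG1 at -0.59. Of 29 genes of the ATF4 and amino acid stress list 14 fell and 6 rose, 15 and 6 over the list alone (adjusted p = 0.025; adjusted p = 0.17 with an estimated correlation). The cystine transporter SLC7A11, undetected in the YAP knockdown, was at least 1.44-fold lower, and CHAC1, which degrades glutathione, stood at -1.33, cystathionase CTH at -1.28 and the glutamine transporter SLC1A5 at -1.07. That call was lost with detection p under 0.01 on all 9 arrays (adjusted p = 0.15). It was also lost with the replicate number as a random block, by camera's preranked form (adjusted p = 0.059). Over the alternatives the adjusted p ranged from 2.9e-04 to 0.17.

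Genes of G1/S and DNA replication were just short of the threshold in the YAP knockdown by camera (adjusted p = 0.060), with 10 of 26 falling and 2 rising, 11 and 2 over the list alone. CDC6, which loads the replicative helicase, changed by -1.69 and RRM2, a subunit of ribonucleotide reductase, by -1.36. The list passed under 14 of the alternatives, among them when control 1, control 2, AMOT knockdown array 3 or YAP knockdown array 1 was left out (adjusted p between 0.037 and 0.048; over the alternatives from 0.0022 to 0.36). In the AMOT knockdown, where CDC6 changed by -1.66 and RRM2 by -1.74, 9 members fell and 3 rose, 10 and 3 over the list alone (adjusted p = 0.20, 0.021 with median scaling, and from 0.0068 to 0.43 over the alternatives).

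**Figure D4:**
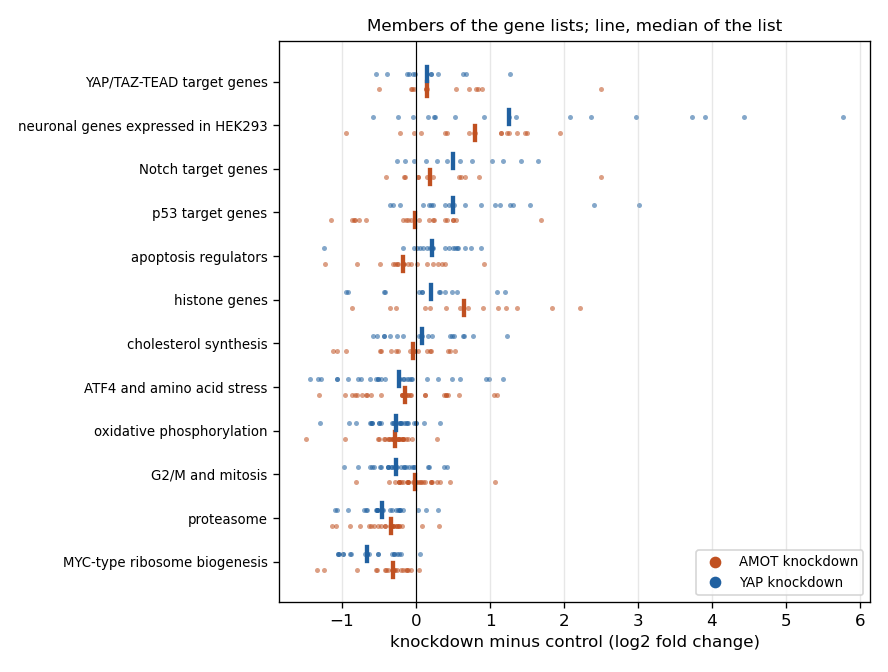
Log2 fold change against controls of each measured member of the gene lists called by camera in any comparison and of the YAP/TAZ-TEAD list, in the AMOT and the YAP knockdown, with points for genes and a thick line for the median of the list. Neuronal medians lay at 0.80 and 1.26, ribosome biogenesis medians at -0.31 and -0.66, and p53 target medians at -0.01 and 0.50.

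Compared directly, the AMOT knockdown had lower BEX1 than the YAP knockdown by 1 probe, at least 43.8-fold (n = 3 per group, adjusted p = 3.0e-09), while another BEX1 probe stood at -0.37 and -0.27 against the controls. CHGB was lower by a log2 difference of -4.28 and GALC by -3.48, STMN2 was at least 12.1-fold lower and the sorting receptor SORCS1 at least 9.43-fold lower. Higher in the AMOT than in the YAP knockdown were MAL2, a protein of apical transport, by at least 3.66-fold, the nuclear body protein SP110 by at least 2.82-fold, the meiotic gene HORMAD1 by at least 4.20-fold, CYP2E1 by 2.52, ZSCAN5A by 2.21 and DPYSL3 by 2.20. The bounds of HORMAD1 and SP110 are those of 1 probe each, and by other probes HORMAD1 was higher by 0.91 and SP110 by 1.24 and 1.81. In total 3904 probes (17.4%) differed, 1926 higher and 1978 lower in the AMOT knockdown. With median scaling 2390 differed, 863 higher and 1527 lower, and the total was 2503 without AMOT knockdown array 1, 2470 without YAP knockdown array 1 and 2554 without YAP knockdown array 2.

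Of the gene lists, 7 were called by camera between the knockdowns. Target genes of p53 were lower in the AMOT than in the YAP knockdown (adjusted p = 5.8e-08; adjusted p = 0.020 with an estimated correlation), 13 of 20 and 16 over the list alone. PHLDA3 differed by -2.15, CDKN1A by -1.90, SESN1 by -1.35 and GDF15 by -1.32. Neuronal genes were lower (adjusted p = 2.4e-04; adjusted p = 0.046 with an estimated correlation), 10 of 17 lower and 3 higher by either count, the 3 being DPYSL3, NCAM1 and UCHL1. Cholesterol synthesis genes were lower (adjusted p = 0.0057; adjusted p = 0.084 with an estimated correlation), 7 of 19 by either count. Among them were INSIG1 at -1.32, ACAT2 at -0.69 and squalene epoxidase, SQLE, at -0.51. Apoptosis regulators were lower (adjusted p = 0.0053; adjusted p = 0.084 with an estimated correlation), 5 of 20 lower and 1 higher, 6 and 1 over the list alone. APAF1 stood at -0.85, BAX at -0.64 and CASP9 at -0.62 (another CASP9 probe at -0.01), and BID higher by 0.39.

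Histone genes were higher in the AMOT than in the YAP knockdown (adjusted p = 1.4e-04; adjusted p = 0.046 with an estimated correlation), 8 of 14 and 9 over the list alone. H4C8 was higher by 1.29 and H2BC5 by 1.13, and H2BC4 and H2AC6, undetected in the YAP knockdown, by at least 1.86-fold and 1.54-fold higher. G2/M and mitosis genes were higher (adjusted p = 1.7e-04; adjusted p = 0.084 with an estimated correlation), 8 of 28 and 14 over the list alone. KIF23 was higher by 0.57, AURKA by 0.54, BUB1 by 0.52 and CDC20 by 0.50. With median scaling none of these 4 differences passed, and that of AURKA also did not pass without YAP knockdown array 1. Ribosome biogenesis genes were higher (adjusted p = 0.014; adjusted p = 0.084 with an estimated correlation), 7 of 21 higher and 2 lower, 10 and 2 over the list alone. NOLC1 was higher by 0.80 and RRP12 by 0.73, and BOP1 and MYC were lower, at -0.28 and -0.46. With median scaling this list was not called (adjusted p = 0.057; over the alternatives from 3.0e-04 to 0.084). The immediate early genes, with 4 of 16 lower (adjusted p = 0.10), passed when AMOT knockdown array 2 was left out (0.031) and by fry, with a range of 0.012 to 0.41 over the alternatives.

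The knockdowns shared most of their changes. HSPB8 rose by 3.34 and 3.08 in the AMOT and YAP knockdowns, CFAP70 by 3.00 and 2.76 and KRTAP19-1 by 2.91 and 4.35. PAQR6 was at least 5.80-fold and 5.61-fold higher, PLA2G4C at least 7.64-fold and 6.46-fold, ISG15 at least 7.64-fold and 5.08-fold and CACNG6 at least 4.73-fold and 4.13-fold. KRCC1 was at least 5.57-fold and 4.57-fold higher by 1 probe, but another of its probes rose by less than that bound in the AMOT knockdown. TOM1L2 changed by -4.29 and -2.94, with another probe at -1.40 and -1.56, RBM14 by -2.29 and -2.42 and SLC43A2 by -2.33 and -2.04. HNRNPA1 changed by -2.17 in each and TRIOBP by -2.19 and -2.09 by 1 probe each, but another probe of HNRNPA1 stood at -0.53 and 0.04 and others of TRIOBP at -0.89 and -0.86 and at -0.13 and 0.44, so the shared fall was not seen on all their probes. BCL2L11, a pro-apoptotic member of the BCL2 family, was undetected in both knockdowns and at least 2.36-fold and 2.35-fold lower by 1 probe, and stood at -1.23 and -1.25 by another. SLC19A1 changed by -2.35 and -1.88 and TKFC by -2.09 and -1.84, each undetected in the AMOT knockdown, where the bounds are at least 4.01-fold and 3.36-fold.

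In all, 5122 probes passed the threshold in both knockdowns in the same direction, 2633 up and 2489 down, where independent sets of these sizes would share 729 and 733. Of these, 972 also differed between the knockdowns. Across probes, which are not independent replicates, the log2 fold changes had a correlation of 0.75 and a covariance of 0.222. Simulated unchanged groups that share the same simulated controls had a mean correlation of 0.50 and a covariance of at most 0.0142.

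**Figure D5:**
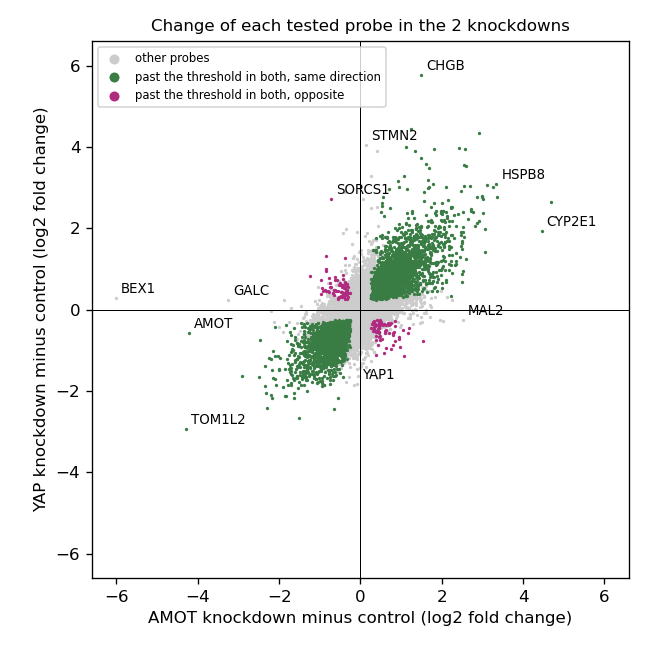
Log2 fold change of each tested probe in the YAP knockdown against that in the AMOT knockdown, both against the same controls, coloured by whether the probe passed the threshold in both with the same or the opposite direction. Of the 5122 probes with the same direction, CHGB among them, 972 also differed between the knockdowns.

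Opposite changes were found for 138 probes, 69 up in the AMOT and down in the YAP knockdown and 69 the other way. Each of them also differed between the knockdowns, which follows from opposite calls because the contrasts share the same standard error per probe. The zinc finger gene ZSCAN5A changed by 1.08 in the AMOT and by -1.13 in the YAP knockdown. HORMAD1 rose by 1.53 in the AMOT knockdown and was at least 1.45-fold lower in the YAP knockdown by 1 probe. Another HORMAD1 probe stood at 0.68 and -0.23, the latter not past the threshold (adjusted p = 0.25). The U1 small nuclear RNA genes RNVU1-7, RNU1-3 and RNVU1-18, near-identical copies that probes may not tell apart, changed by 0.98, 0.80 and 0.85 in the AMOT and by -0.93, -0.87 and -0.77 in the YAP knockdown. In the other direction the sterol sensor INSIG1 changed by -0.85 and 1.00, with another probe at -0.09 and 1.23, TMEM100 by -0.84 and 0.95, the collagen COL5A2 by -1.24 and 0.82, GID4 of chromosome 17 by -0.77 and 0.78, and PHLDA3 by -0.84 and 1.31. The fall of PHLDA3 in the AMOT knockdown did not pass without control 2 or 3 or AMOT knockdown array 1 or 2, and the fall of HORMAD1 in the YAP knockdown did not pass without control 1 or 3 or YAP knockdown array 2.

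Of the marker lists of other cell types, camera called none. By fry, which does not compare a list with other genes, the fibroblast list passed in each comparison (adjusted p = 0.0091, 8.0e-04 and 0.025 between them). By fry the hepatocyte list passed in the AMOT knockdown (0.0055), and the keratinocyte and carcinoma list there (0.0055) and between the knockdowns (0.0069). Of 6 fibroblast markers 2 rose in each knockdown, LUM and FBLN1 in the AMOT and COL3A1 and FBLN1 in the YAP knockdown (adjusted p = 0.73 and 0.63, and 0.59 between them). The LUM call did not pass without control 1 or 3 or AMOT knockdown array 1 or 3, and the COL3A1 call not without control 2 or 3 or any 1 of the 6 knockdown arrays. Of 3 hepatocyte markers ALB and APOA1 rose in the AMOT knockdown, by 0.72 and 0.90, and APOA1 by 0.91 in the YAP knockdown (adjusted p = 0.22, 0.63 and 0.59), the ALB call not passing without AMOT knockdown array 1. Of 4 blood cell markers CD14 rose by 0.61 in the AMOT knockdown and stood at -0.01 in the YAP knockdown (adjusted p = 0.89, 0.66 and 0.75). Of the keratinocyte and carcinoma markers only EPCAM and CDH1 were measured, and CDH1 stood at -0.94 and -0.99 (adjusted p for the list 0.73, 0.83 and 0.29). The CDH1 call did not pass in the AMOT knockdown without control 3 or AMOT knockdown array 1 or 2, nor in the YAP knockdown without YAP knockdown array 3. Of 7 kidney lineage genes EYA1 and PODXL rose in the AMOT knockdown, by 0.64 and 0.44, PODXL rose by 0.53 in the YAP knockdown, and WT1 stood at -0.49 and -1.08, past the threshold in both (adjusted p = 0.73, 0.89 and 0.53).

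Of 15 housekeeping genes 2 rose and 6 fell in the AMOT knockdown and 2 rose and 3 fell in the YAP knockdown (adjusted p = 0.20, 0.63 and 0.39 between them). ACTB stood at -0.61 and -0.42, the latter not passing with median scaling or without control 1 or YAP knockdown array 1. The remaining lists were called in no comparison by camera, the camera adjusted p of the uncalled lists lying between 0.14 and 0.94 in the AMOT knockdown, 0.060 and 0.89 in the YAP knockdown and 0.10 and 0.93 between them. By fry 26, 23 and 21 of the 34 lists passed in these comparisons, many of the uncalled lists among them. Among these lists median, mean and test differed in sign for 4 lists in each knockdown and for 6 between them, all of them uncalled. In the interferon list ISG15 was at least 7.64-fold and the restriction factor BST2 at least 1.68-fold higher in the AMOT knockdown, while 4 of 16 members rose and 3 fell (camera adjusted p = 0.64, fry 0.0017). In the YAP knockdown 6 rose and 3 fell (camera adjusted p = 0.63, fry 5.3e-04). Of the BMP target genes ID3 stood at -0.95 and -1.87, and of the actin and SRF list TAGLN rose by 1.63 and 2.04.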

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

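Here the scan of neighbouring genes and the tests of the shared control noise, the vector, REST, neuronal cells and DNA copies were chosen only after the results were seen. The following differed between the AMOT and the YAP knockdown by a test of the difference itself, with 3 arrays per group. Opposite changes past the threshold in both knockdowns were found for 138 probes, for which a difference follows from the opposite calls themselves. The median difference, AMOT minus YAP knockdown on the log2 scale, was -0.686 for the p53 target list and -0.576 for the neuronal list. ANKRD1 differed by 1.83, CCN2 by 1.233 and CCND1 by -1.811.

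The counts behind these comparisons were also obtained for other splits of the same 6 arrays. The real split was the 1 of 10 that reached 7846 probes in the AMOT knockdown, 8338 in the YAP knockdown and 3904 between them, and the highest other split gave 0 by limma in each (at unadjusted p under 0.05, 1274, 1050 and 1138 against 10001, 10313 and 7034). For gene lists the real counts of 5, 8 and 7 were again reached by 1 of 10 splits, with 4, 6 and 4 in the highest other. With 10 splits, a share under 0.05 cannot be reached. Each other split also puts arrays of both groups together, which widens the spread within groups and lowers its count of probes.

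The changes common to both knockdowns were weighed first. Of 100 splits of the 9 arrays into 3 groups, 1, the real one, reached 5122 shared probes, and the highest other reached 417. Other splits put arrays of different groups together, which widens the spread within groups and lowers the count whatever the cause. A split by chance is therefore not excluded by these counts. Independent noise of shared control arrays, at the spread pooled over the groups, was excluded by a covariance of 0.222 against at most 0.0142 in simulated unchanged groups. The simulated controls held no noise common to several probes or arrays, so control noise of that kind was not tested. A trend with brightness as the whole cause was excluded by the 5097 shared probes after cyclic loess. Vector, selection or handling common to both hairpin lines may account for the shared changes. They cannot be told apart from a common effect of lowering AMOT or YAP1, because no control hairpin was labelled. The component that parts both knockdowns from the controls held 50.1% of the variance.

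The neuronal genes higher in the YAP knockdown were weighed next. The list's median of 1.26 lay at percentile 100 of 10000 random lists matched on mean level over all 9 arrays, whose highest was 0.695. That level includes the YAP knockdown arrays themselves, so the random lists need not be as dim in the controls. A general rise of probes dim in the controls was therefore not excluded. Loss of the REST transcript, a repressor of neuronal genes, stays open, as its probe stood at -0.159 (SE 0.281) with a mean level of 6.01 near the detection floor of 5.88. Neuronal cells among the samples also stay open: 2 of 7 members not detected on all controls, GAP43 and DPYSL3, were not called higher, while 10 of the 17 members were detected on all controls and so are expressed by this line itself. The same list was also higher in the AMOT knockdown, where its median of 0.803 lay at percentile 100 and the highest random list reached 0.735. YAP1 stood at -0.08 there (limma adjusted p = 0.57). Vector, selection or handling common to both hairpin lines therefore also stays open for the part of the rise seen in both. An effect of lowering YAP1 may account for the rise in the YAP knockdown, and no test set it apart from these.

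The low stretch of chromosome 17 in the AMOT knockdown was weighed last. Wholly random placement of changed genes was excluded, since the lowest running median of 21 neighbouring genes was -1.005 and the lowest of 1000 shuffled orders was -0.592. Shuffling breaks any likeness between neighbouring genes, so it does not show why neighbours moved together. Loss of DNA copies in the AMOT knockdown line is a candidate explanation that stays open, with a median log2 change of -0.608 over the stretch and no DNA measured. TOM1L2, ALDH3A2, B9D1 and ATPAF2 may therefore owe part of their fall to copy number, although by these probes all 4 fell in the YAP knockdown too (-2.94, -1.67, -1.39 and -1.21; by other probes TOM1L2 stood at -1.56, ALDH3A2 at -0.44 and -0.36 and B9D1 at -1.22), where no stretch went beyond the shuffled orders.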

How the results depend on the processing

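Leaving out chromosome 17 genes was the alternative chosen only after the data were seen; the others were planned. In total 27 settings were run, 9 of them leaving out 1 array each.

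The AMOT transcript in its knockdown ranged from -4.35 to -4.04 and the YAP1 transcript in its own from -1.87 to -1.53, past the threshold each time. At adjusted p 0.01 the counts were 4712 probes for the AMOT knockdown, 5149 for the YAP knockdown, 1728 between them and 2901 changed the same way. With at least 1.5-fold asked they were 4329, 4643, 1989 and 2526. Both settings are stricter by construction. Median scaling gave 2390 probes between the knockdowns, and the cause was not tested. Leaving out 1 array gave 2470 to 3982 between the knockdowns (2503 without AMOT knockdown array 1, 2470 without YAP knockdown array 1 and 2554 without YAP knockdown array 2), 6246 to 7498 for the AMOT knockdown, 6620 to 8189 for the YAP knockdown and 4002 to 4639 changed the same way. The remaining settings gave 5896 to 8759, 6281 to 9142, 3020 to 4913 and 3558 to 5883 in that order.

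Gene lists called were 0, 2 and 3 by camera with an estimated correlation in the AMOT knockdown, the YAP knockdown and between them (5, 8 and 7 at unadjusted p under 0.05), and 26, 23 and 21 by fry, which does not compare a list with other genes. Other settings gave 5 to 7, 7 to 9 and 6 to 8, with 7, 7 and 8 for the random block by camera's preranked form. The hypoxia and glycolysis list in the YAP knockdown, not called by camera (adjusted p = 0.84), took the other direction by fry (adjusted p = 0.00308); the cause was not tested.

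With the replicate number as a fixed replicate block the counts were 7233, 7837, 3304 and 4679, and as a random replicate block 7594, 8094, 3663 and 4935, at a consensus correlation of -0.0398. Of 425 named gene results, 346 kept their side of the threshold in every setting tried for them, and no called result reversed direction. The stricter adjusted p and the minimum fold change were not applied to these results. A setting whose filter left out a gene's probe was not tried for that gene, which concerns genes undetected in a group. Where a result was uncalled both in the main fit and in a setting, a change of sign was not counted. The slide block was not run, as no column names a slide, and dim signals near the background limit what can be said of genes undetected in a group.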

Other observations

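The gene families and the scan of neighbouring genes named here were chosen after the values were seen. Of 8 measured keratin-associated genes, which encode proteins of the hair shaft, 5 rose in the AMOT knockdown and 6 rose and 1 fell in the YAP knockdown, with medians of 1.70 and 3.33, and 6 were lower in the AMOT than in the YAP knockdown. Of 4 measured U1 small nuclear RNA genes, 3 rose in the AMOT knockdown and 3 fell in the YAP knockdown, with medians of 0.83 and -0.82. Their probes may not tell these near-identical copies apart, so the counts need not be of separate genes.

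BEX1 was 1 of 11 measured genes of the BEX and TCEAL families, small proteins encoded together on chromosome X. Of their 19 probes 5 rose and 1 fell in the AMOT knockdown, and 4 rose and 1 fell in the YAP knockdown. On chromosome 10, the 21 genes from FRMD4A to NEBL, VIM among them, had a median difference of 0.54 between the knockdowns, and the highest of the shuffled orders was 0.533. On chromosome 17 the same scan gave MPRIP to SDF2, which overlaps the first stretch above, and the 26 genes from RPL23A to SMURF2P1-LRRC37BP1. The latter had medians of -0.25 in the AMOT knockdown, where 11 fell and 0 rose, and 0.32 in the YAP knockdown, where 12 rose and 5 fell.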
